A study of Rattus norvegicus with 12 samples.

How the data were processed

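Messenger RNA was measured in primary rat (Wistar) aortic smooth muscle cells of 2 genotypes, each grown static or under cyclic stretch. WT cells carried an intact Thbs1 gene, which encodes the matricellular protein thrombospondin-1 (Tsp1). The Tsp1 KO cells were made with a plasmid coding for Cas9, GFP and a guide RNA, sorted by GFP and grown out from single cells by limiting dilution, per the labels. How many clones were used is not stated. Cells were grown in 20% serum at passages 5 to 8 on silicone elastomer plates. After 24 h of serum starvation the stretched cells received uniaxial stretch of 20% strain at 1.0 Hz, or 60 cycles per minute, and the duration is not given. Each of the 4 groups has 3 libraries, so 12 in all. Nothing in the labels says that the 3 libraries of a group came from separate cultures. All p-values therefore measure only the spread between these samples, which may be technical.

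Per the labels, the authors extracted RNA with TRIZOL, selected poly(A) RNA from 500 ng, made directional libraries and sequenced paired ends of 36 bases on a NextSeq 500. The authors mapped the reads to the rat build Rnor_6.0 with CLC Genomics Workbench 12.0. The deposited read counts are whole numbers of reads in the annotated exons of each gene, and per the file headers multi-mapped reads are part of the total exon count and left out of the unique exon count. The deposited RPKM values are exon reads per kilobase of exon and 1e6 mapped reads, and 1 constant per library related them to the counts. The deposited table also holds the authors' fold change, a signed score in which a negative value is minus the reciprocal. Its p-value columns used here are the authors' false discovery rates from the CLC EDGE test with tagwise dispersions. Strand setting, trimming and annotation release are not stated. The table lists 22081 genes, and 35 of them have an exon length of 0.

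Total exon reads were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with a minimum count of 10, which left 14825 genes, scaling was by TMM, and 1 model with a mean for each of the 4 groups was fitted to all 12 libraries with 8 residual degrees of freedom. Comparisons used the quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes (FDR). A gene was counted as changed at FDR under 0.05, and separately when it also changed at least 2-fold. The 5 comparisons were stretch against static in each genotype, KO against WT in each condition, and the difference between the genotypes' stretch responses (interaction). Levels are counts per 1e6 reads (CPM) with the SD of 3 libraries, and log2 fold changes carry their SE. The precision of a level is set by the libraries' 16.8e6 to 38.0e6 exon reads and by the spread of 3 samples.

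The genes, the lists, the model and the alternatives were chosen before the data were examined, except where stated. Genes are named by a fixed rule. Thbs1 is named in every comparison. Each pairwise comparison names the 10 largest rises and 10 largest falls among genes with FDR under 0.05, a mean log2 CPM of at least 2, groups that do not overlap (chance parts 3 against 3 in 10% of unchanged genes) and a named symbol. A gene list names up to 4 members with the largest change past the threshold, or otherwise 2 highest-level members. Some genes these rules pick are not reported here. For the interaction the rule allowed 5 genes per direction, and 0 met it. Genes with a large share of multi-mapped reads are reported as uncertain.

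The 28 gene lists cover YAP/TAZ targets, Hippo components, contractile smooth muscle genes, actin and focal adhesion genes, integrins, immediate early genes, collagens, elastic fibre genes, thrombospondins and other matricellular genes, matrix proteases and their inhibitors, TGF-beta response, cytokine and NF-kB response, interferon response, cell cycle, p53 targets, unfolded protein and integrated stress response, heat shock, NRF2 targets, cholesterol synthesis, glycolysis and hypoxia, mitochondrially encoded genes, ribosomal proteins, and markers of fibroblasts, endothelium, leukocytes, osteochondrogenic cells, epithelium and adipocytes. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 3 and a preset correlation of 0.01 between genes, adjusted over 140 tests (28 lists in 5 comparisons). The same test with an estimated correlation, and fry, were run beside it. List sizes are of tested members. Some members were not analysed here and some fell below the filter.

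The library numbers 1 to 3 were checked for pairing across the groups. After removal of the group means, libraries numbered 1 correlated across genes at r = 0.16 to 0.23 and those numbered 2 at 0.12 to 0.26. Those numbered 3 correlated at 0.40 to 0.56 (6 pairs of libraries for each number), and libraries of different number at -0.40 to 0.29 (36 pairs). Only number 3 therefore stood clear as a set. The best partner in the other groups had the same number for 4 libraries, all numbered 3. The same-number correlations still met the rule set for a second fit with the number as a block, which has 6 residual degrees of freedom. Results with this block are given beside the others where it changes a call or moves a count by more than 1.5 times. Other alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, filters, unique reads, limma-trend on log2 RPKM with pseudocounts of 0.1, 0.5 and 1, only the 2 groups compared, leaving out each library, and list tests without members of more than 1 list. The last left the lists as they were because no tested gene is in more than 1. A 2-level block for number 3, a fit without number 3, and removal of a trend with exon length were added after the data were seen.

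The tests were run on simulated data with the number effects kept and 200 changed genes. The counts were drawn from the fit with the block, with its dispersions and the same number effects in all 4 groups. A higher recovery with the block was therefore built in. Without the block, edgeR recovered 22.4% of 1.5-fold, 76.1% of 2-fold and 100% of 4-fold changes for the stretch comparison in WT, with 0 false calls (DESeq2 also 0), and with the block 79.1%, 98.5% and 100% with 12 false calls. For the interaction, it recovered 1.49%, 32.8% and 89.4% without the block, and 50.7%, 92.5% and 100% with it, with 14 false calls. For KO against WT in static culture it recovered 11.9%, 73.1% and 97.0% without the block. Camera gave a p under 0.05 for 1.2% of 1000 random lists of 20 genes. Apart from the number effects the simulated genes varied independently, so this share does not test the preset correlation for genes regulated together.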

Results

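RNA sequencing measured gene expression in rat aortic smooth muscle cells with an intact Thbs1 gene (WT) or after CRISPR knockout of it (KO), each kept static or stretched cyclically. Each of the 4 groups has 3 libraries. The total of exon reads in libraries 1, 2 and 3 was 24.7e6, 16.8e6 and 24.1e6 in WT static, 25.5e6, 28.5e6 and 29.4e6 in WT stretch, 18.6e6, 24.1e6 and 38.0e6 in KO static, and 24.5e6, 19.9e6 and 35.5e6 in KO stretch. The comparisons ask what stretch changes in these cells, what loss of Tsp1 changes, and whether the response to stretch differs without Tsp1. KO cells were grown from single cells, so a difference between KO and WT cannot be separated here from a difference between clones.

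Thbs1 (ENSRNOG00000045829, chromosome 3 from 109862117 to 109873466 in Rnor_6.0) encodes thrombospondin-1, a secreted matrix protein, and was among the well-expressed genes of WT static cells at 2661 ± 547 CPM (SD, n = 3). KO static cells held 556 ± 101 CPM, a log2 fold change of -2.26 ± 0.24 (SE, FDR 3.96e-05). Under stretch the level was 1437 ± 342 CPM in WT and 379 ± 83.6 CPM in KO cells, a log2 fold change of -1.92 ± 0.24 (FDR 0.000129). Reads on Thbs1 therefore remained in every KO library, and the place of the edit is not given, so the counts do not show what protein these transcripts can make. Stretch gave a log2 fold change of -0.89 ± 0.23 in WT (FDR 0.156, and 2.88e-05 with the replicate block) and of -0.55 ± 0.23 in KO cells (FDR 0.576, and 0.000609 with the block). The interaction was 0.33 ± 0.33 (FDR 1.00, and 0.506 with the block). The authors' signed fold changes were -4.78 and -3.80 for KO against WT, -1.84 for WT stretch (FDR 0.0288) and -1.46 for KO stretch (FDR 0.789).

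**Figure D1:**
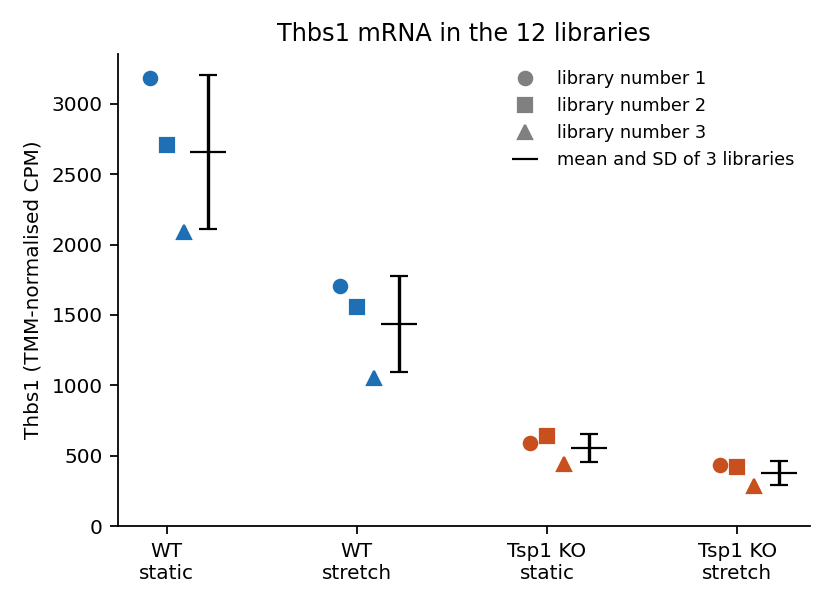
Thbs1 level in counts per 1e6 reads in each of the 12 libraries, with the group mean and SD of 3 libraries. Markers give the library number. All 6 KO libraries (283 to 637 CPM) lie below all 6 WT libraries (1052 to 3183 CPM).

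The libraries differed by genotype first, by library number second and by stretch only after these. Principal component 1 held 49.6% of the variance and parted the genotypes, component 2 held 17.8% and parted the libraries numbered 3 from the others, and component 3 held 5.93% and parted stretch from static. Between number 3 and numbers 1 and 2 across the groups, 7427 genes differed (3577 higher in number 3), while number 2 against number 1 gave 0 genes in the same edgeR test. Long genes were lower in number 3. Across genes, Spearman's rho of the difference with exon length was -0.56, with a median log2 fold change of 0.29 in the shortest 25% of genes and -0.30 in the longest. In number-3 libraries 9.15% to 11.3% of gene reads fell in introns, against 14.8% to 16.5% in the others. KO stretch library 3 also stood apart by the share of exon reads that spanned exon junctions (16.4%, others 28.1% to 29.8%) and by uniquely mapped exon reads (83.1%, others 86.5% to 89.1%). A block for library number lowered the common dispersion from 0.0437 to 0.0096.

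Stretch of WT cells lowered cholesterol synthesis genes as a list and changed single genes in both directions. Among the genes named by the fixed rule, which needs a mean log2 CPM of at least 2, the largest rise was in Tnfaip6 (ENSRNOG00000050792, chromosome 3 from 37545238 to 37564699), a secreted hyaluronan-binding protein of inflamed tissue, from 11.8 ± 0.816 to 38.3 ± 2.12 CPM (log2 fold change 1.70 ± 0.11, FDR 7.41e-05). Aldh1a3, which makes retinoic acid, rose from 15.6 ± 1.05 to 38.0 ± 4.44 CPM (1.28 ± 0.13, FDR 0.00241), and Csrp2, a LIM protein of smooth muscle, from 48.3 ± 4.94 to 107 ± 12.4 CPM (1.15 ± 0.17, FDR 0.0120). The adhesion molecule Mcam, the clock factor Arntl2, the kinase Stk38l, the phosphatase Dusp8 and the NADPH oxidase Nox1 also rose, by log2 0.85 to 1.12. Nox1 lies beside Cstf2 with overlapping ends, and Cstf2 rose by log2 0.84, so the Nox1 rise may not be its own. The other named rises, Cxcl10 and Angptl2, are uncertain, because only 38.1% and 29.4% of their exon reads mapped uniquely. Cilp, a matrix protein of cartilage, had the largest fall of these genes, from 4.87 ± 0.54 to 1.89 ± 0.41 CPM (-1.36 ± 0.18, FDR 0.00801). Adamts15, Parm1, the anticoagulant receptor Thbd, the sterol reductase Dhcr7, the fatty acid desaturase Scd, Lmo7 and the flow-responsive factor Klf2 fell, with log2 fold changes of -1.2 to -0.94.

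In WT cells 110 genes changed with stretch at FDR 0.05 (41 up, 69 down), and 27 of them at least 2-fold (9 up, 18 down), with 1403 genes at an unadjusted p under 0.05. With the replicate block 944 genes changed (404 up, 540 down), 59 of them at least 2-fold. Upper-quartile scaling moved the balance to 24 up and 69 down. The authors' own test has 78 genes at FDR 0.05, of which 39 changed at least 2-fold (15 up, 24 down). Without any 1 of the 6 libraries compared the count fell to between 23 (without WT stretch 2) and 54 (without WT stretch 3), with 35, 41 and 45 without WT static 1, 2 and 3, and 31 without WT stretch 1. Tnfaip6, Aldh1a3, Arntl2, Stk38l, Cilp, Parm1 and Thbd kept FDR under 0.05 whichever of the 12 libraries was left out. Nox1 lost it when any of 9 libraries was left out, Dusp8 and Klf2 for any of 7, and Scd for any of 5. For Mcam and Adamts15 it was any of 4, and for Csrp2 and Dhcr7 any of 3.

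Cholesterol synthesis genes formed the strongest list in WT stretch. Of 23 members 11 fell and 0 rose over all genes, 22 fell adjusted over the list alone, the median log2 fold change was -0.60, and camera gave an adjusted p of 2.06e-30 (adjusted p = 0.0129 with an estimated correlation, 0.246 with the block as well). Dhcr7, Insig1 and Hsd17b7 were among the falls, and with the block 20 members fell. Uniquely mapped reads were 49.1% for Insig1 and 47.0% for Hsd17b7. Heat shock genes leaned up, with a median of 0.24 over 16 members (adjusted p = 4.45e-06, adjusted p = 0.225 with an estimated correlation). Among these the co-chaperone Hsph1 rose (0.72 ± 0.08), 5 rose adjusted over the list alone, and 7 rose with the block.

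Weaker shifts in WT stretch rested on a few libraries and were lost with an estimated correlation. YAP/TAZ targets leaned down (21 members, Amotl2 fell at -0.68 ± 0.10, 3 fell adjusted over the list alone, adjusted p = 0.00963, adjusted p = 0.562 with an estimated correlation). Collagens leaned down (0 of 19 passed, median -0.19, adjusted p = 0.000728 and 0.640 with an estimated correlation), as did NRF2 targets (0 of 15, 2 fell adjusted over the list alone, 0.0108 and 0.566). Ribosomal proteins (0 of 26, median 0.24, 0.00153 and 0.849), interferon response genes (0 of 21, median 0.19, 0.00408 and 0.635) and mitochondrially encoded genes (0 of 13, median 0.20, 0.00408 and 0.615) leaned up. Without WT stretch 3 the adjusted p was 0.218 for YAP/TAZ targets, 0.286 for collagens, 0.0871 for interferon and 0.742 for ribosomal proteins. Without WT static 1 it was 0.108, 0.0541 and 0.177 for YAP/TAZ, collagens and ribosomal proteins. NRF2 targets lost theirs without WT stretch 1 (0.178), WT stretch 2 (0.0681) or WT static 3 (0.156), and mitochondrial genes without WT static 3 (0.0769). In libraries numbered 1 and 2 alone YAP/TAZ targets had 0.0825, collagens 0.125, interferon 0.0986 and mitochondrial genes 0.098. The WT stretch response fell with exon length over all genes (Spearman's rho -0.18, and -0.05 in KO stretch), and with the length trend removed and the block mitochondrial genes had 0.0517.

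Immediate early genes moved both ways in WT stretch, with Dusp1 (0.77) and Jun up and Egr2 (-1.1), Klf2 (-0.94) and Egr1 (-0.73) down, so 2 rose and 3 fell of 25 (5 and 6 adjusted over the list alone, adjusted p = 0.723). Single members of other lists passed while the list did not. The contractile regulator Cnn1 rose from 101 ± 9.45 to 170 ± 17 CPM (0.75 ± 0.14, list adjusted p = 0.0982, 3 of 21 rose adjusted over the list alone). The focal adhesion kinase Ptk2 (0.54, actin and focal adhesion list 0.381), the crosslinker Loxl1 (0.75, elastic fibre list 0.543) and Btg2 (0.63, p53 list 0.0997, 0.0128 with the block, and 0.313 with the block and an estimated correlation) rose. The integrins Itga3 (-0.68) and Itga7 (-0.46, list 0.147), the chemokine Cxcl12 (-0.58, cytokine list 0.548) and Car9 (-0.54, glycolysis and hypoxia list 0.548) fell. Cell cycle genes had 0 of 26 past FDR and an adjusted p of 0.09996 (0.0356 with the block, 0.707 with an estimated correlation as well). Without the block no gene passed among matricellular genes (0.994), matrix proteases (0.627), TGF-beta response (0.782), Hippo components (0.306), stress response (0.534) and markers of fibroblasts (0.701), endothelium (0.837), leukocytes (0.350), osteochondrogenic cells (0.114), epithelium (0.450) and adipocytes (0.671), with the adjusted p of each list in parentheses. With the block more members passed, among them 1 rise and 4 falls of YAP/TAZ targets, 1 and 5 of Hippo components, 4 and 1 of actin genes, 1 and 4 of integrins, 0 and 3 of collagens, 4 and 2 of proteases, 1 and 3 of TGF-beta genes, 3 and 4 of cytokine genes and 0 and 5 of NRF2 targets. There were also 3 and 0 of contractile, 5 and 4 of immediate early, 3 and 2 of elastic fibre, 2 and 0 of matricellular, 2 and 0 of p53, 1 and 0 of interferon, 1 and 1 of stress response and 1 and 2 of glycolysis genes, and 0 and 2 of fibroblast and 0 and 1 of endothelial markers. The test fry gave p53 targets up (adjusted p = 0.0167).

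Stretch of KO cells lowered cholesterol synthesis genes as a list and changed single genes in both directions. Cav3, the muscle caveolin, fell from 4.66 ± 0.642 to 1.79 ± 0.417 CPM (ENSRNOG00000005798, log2 fold change -1.37 ± 0.21, FDR 0.0164), and Mybphl, a myosin-binding protein, from 8.08 ± 0.167 to 3.31 ± 0.372 CPM (-1.29 ± 0.13, FDR 0.00198). Cilp, the inflammasome sensor Nlrp3, Dhcr7, Scd, Insig1, Acat2 and Depp1 fell with log2 fold changes of -1.26 to -1.08. The connexin Gja4 (1.17 ± 0.20, FDR 0.0270) and Mcam (13.2 ± 1.86 to 29.5 ± 3.03 CPM, 1.16 ± 0.14, FDR 0.00427) had the largest rises of the genes named by the rule, and Tnfaip6 rose from 19.9 ± 2.07 to 37.1 ± 2.40 CPM (0.90 ± 0.10, FDR 0.00375). Mill1, Il1rl1, the clock repressor Cry1, the oxygen sensor Egln3, Cstf2, Mindy4 and Ppid rose by log2 0.68 to 0.83. Unique reads were 15.4% for Depp1, 31.8% for Ppid, 49.1% for Insig1 and 76.7% for Acat2, so these are uncertain, and Cstf2 lies beside Nox1 with overlapping ends.

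In KO cells 118 genes changed with stretch at FDR 0.05 (31 up, 87 down), 28 of them at least 2-fold (4 up, 24 down), with 1153 at an unadjusted p under 0.05. With the replicate block the count was 656 (209 up, 447 down), 53 of them at least 2-fold. The authors' test has 101 genes, of which 54 changed at least 2-fold (24 up, 30 down). The count was 51, 38 and 55 without KO static 1, 2 and 3, then 37, 24 and 62 without KO stretch 1, 2 and 3, and 66 without WT stretch 2. Mcam, Tnfaip6, Mybphl, Cilp, Dhcr7, Insig1 and Acat2 kept FDR under 0.05 whichever library was left out. Cry1 and Mindy4 lost it when any of 10 libraries was left out, and Il1rl1, Egln3 and Ppid for any of 8. For Gja4 it was any of 7, for Mill1 any of 6, for Depp1 any of 5, for Nlrp3 any of 4 and for Cav3 any of 3.

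Of the 23 cholesterol synthesis genes 16 fell and 0 rose in stretched KO cells, 22 fell adjusted over the list alone, and the median log2 fold change was -0.84 (adjusted p = 1.16e-49, adjusted p = 0.00929 with an estimated correlation, 0.149 with the block as well). Dhcr7 fell at -1.21 (FDR 0.00429). Contractile genes leaned down, with a median of -0.26 over 21 members (adjusted p = 1.79e-05, adjusted p = 0.0504 with an estimated correlation). Lmod1, which nucleates actin filaments, fell from 86.4 ± 4.63 to 60.7 ± 0.139 CPM (-0.51 ± 0.08), 4 members fell adjusted over the list alone, and 8 fell with the block. Among YAP/TAZ targets F3 (-1.75), Amotl2 (-0.78) and Ccn1 (-0.66) fell, 4 fell adjusted over the list alone (adjusted p = 5.03e-05, adjusted p = 0.330 with an estimated correlation). NRF2 targets leaned down (Txnrd1 fell at -0.37, 3 of 15 fell adjusted over the list alone, 0.000954 and 0.423 with an estimated correlation).

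The other lists of KO stretch with an adjusted p under 0.05 lost it when some libraries were left out. Cell cycle genes (0 of 26 passed, 0.00316, 0.289 with an estimated correlation) had 0.0575 without KO static 2. Mitochondrially encoded genes (0 of 13, 0.00882 and 0.635) had 0.607 without KO static 3 and 0.521 in numbers 1 and 2 alone. Heat shock genes, with Hsph1 up by log2 0.64, had 0.0143 (0.566 with an estimated correlation), 0.107 without KO static 1, 0.294 without KO stretch 3 and 0.0591 in numbers 1 and 2 alone. Integrins, with Itga3 down at -0.92, had 0.0454 (0.663 with an estimated correlation, 0.0801 with the block). Their adjusted p was 0.0522 and 0.0559 without WT static 1 and 2, 0.0608 and 0.0580 without WT stretch 1 and 3, 0.106 and 0.209 without KO static 1 and 2, and 0.425 without KO stretch 3. With the block, collagens (0.0386) and actin and focal adhesion genes (0.0131) leaned down and matricellular genes up (0.0371), from 0.175, 0.189 and 0.172 without it, and an estimated correlation with the block gave 0.887, 0.707 and 0.313. The block raised the falls to 7 of YAP/TAZ targets, 6 of immediate early genes (with 4 rises), 4 each of Hippo, actin, TGF-beta and NRF2 genes, 3 each of cytokine genes (with 1 rise) and fibroblast markers, 2 each of integrins, collagens, cell cycle genes and epithelial markers (the last with 1 rise), and 1 each of p53, stress response and glycolysis genes (each with 1 rise). It gave 2 rises each of elastic fibre, matricellular and heat shock genes and 1 each of proteases and interferon genes. Fibroblast markers had 0.194 with camera, 0.0237 on log2 RPKM and 0.00995 (down) with fry. Ribosomal proteins had 0.662, but between 0.00333 (without KO static 3) and 0.737 without single libraries, and without KO stretch 3 the list changed direction with 0.0342. Members that passed in lists that did not included Ptk2 (0.44), Dusp1 (0.61) and Pmepa1 (0.62) up, and Arc (-1.43), Egr1 (-0.74), Wwc1 (-0.70), Icam1 (-0.64) and Cxcl12 (-0.43) down, which is not the full set.

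The genes that changed with stretch in WT and in KO cells overlapped far more than independent lists would. Both shared 15 rises and 37 falls, where independent lists would share 0.0857 and 0.405, and 0 genes changed in opposite directions. With the replicate block they shared 123 rises and 256 falls, and 1 gene was opposite. Leaving out 1 library lowered the shared count from 52 to between 15 (without WT stretch 2) and 37. Over the 27 genes that changed at least 2-fold in WT, 24 had the same sign in KO, and the slope of the KO on the WT response was 0.63. From the libraries numbered 1, 2 and 3 taken singly it was 0.401, 0.579 and 0.517, each below that value. Over the 28 genes so changed in KO, 27 had the same sign in WT and the reverse slope was 0.72 (0.723, 0.580 and 0.763 by number). Each slope was fitted to genes chosen for a large change in the genotype on the x axis, which by itself pulls it below 1. Leaving out 1 library gave slopes from 0.246 (without KO stretch 1) to 0.654 and, in reverse, from 0.182 (without KO static 3) to 0.924 (without KO stretch 2), and also 0.328 without WT stretch 1. The first slope was 0.397 without WT static 3. It was 0.122 in DESeq2, and the reverse slope there was -0.0315, so neither slope gives a firm size for the difference.

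**Figure D2:**
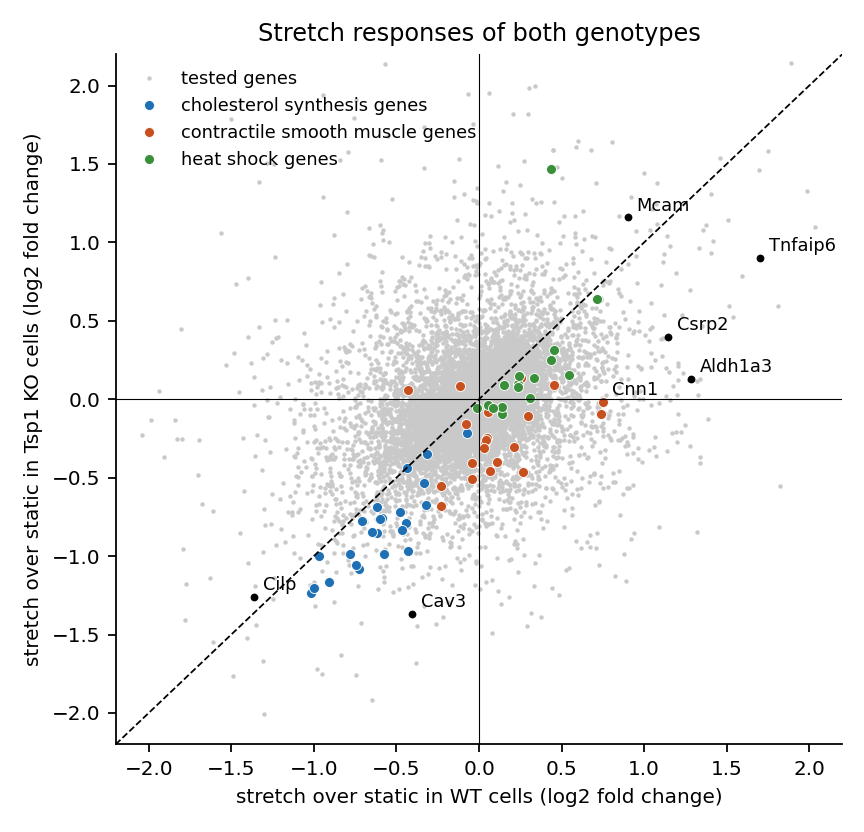
Log2 fold change with stretch in WT (x axis) and KO cells (y axis) for the 14825 tested genes, of which 79 lie outside the axes. The dashed line marks equal responses, and 23 cholesterol synthesis genes (blue) lie below 0 on both axes.

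No single gene passed the test of a different stretch response between the genotypes. edgeR gave 0 genes, with 336 at an unadjusted p under 0.05 and a smallest FDR of 0.827, while DESeq2 gave 9 genes (4 at least 2-fold). With the replicate block 2 genes passed, Aldh1a3 and Vegfc, which are named here after their values were seen. Aldh1a3 rose in WT (1.28 ± 0.13) and gave 0.13 ± 0.13 in KO cells, where its level was 28.0 ± 3.97 CPM static and 30.6 ± 3.28 CPM stretched (interaction -1.15, FDR 0.00357 with the block and 0.827 without). Vegfc, a vascular growth factor, fell in WT (-0.57 ± 0.09) and gave 0.17 ± 0.09 in KO cells (interaction 0.74, FDR 0.0353 with the block and 0.827 without). In simulated data edgeR recovered 32.8% of 2-fold and 1.49% of 1.5-fold interactions without the block, and 92.5% and 50.7% with it. The fit with the block also gave 14 false calls for the interaction there, and the fit without it gave 0. The simulated counts came from the fit with the block, so its gain was built in. In that setting the test without the block missed most such differences of single genes.

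Contractile smooth muscle genes as a list responded lower in KO than in WT cells. The median interaction of the 21 members was -0.36, and 19 members lay below 0 (adjusted p = 4.06e-11, adjusted p = 0.0129 with an estimated correlation, 0.246 with the block as well). Over all genes 0 members passed (edgeR), while 4 fell adjusted over the list alone and 13 did so with the block. Acta2, smooth muscle actin, was 2168 ± 180 CPM in WT static, 2268 ± 138 in WT stretch, 1255 ± 114 in KO static and 915 ± 110 in KO stretch (interaction -0.52 ± 0.16, FDR 1.00). Tagln gave an interaction of -0.40 ± 0.24 (FDR 1.00). With the preset correlation the call held without each of the 12 libraries. The estimated correlation was not run with libraries left out.

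**Figure D3:**
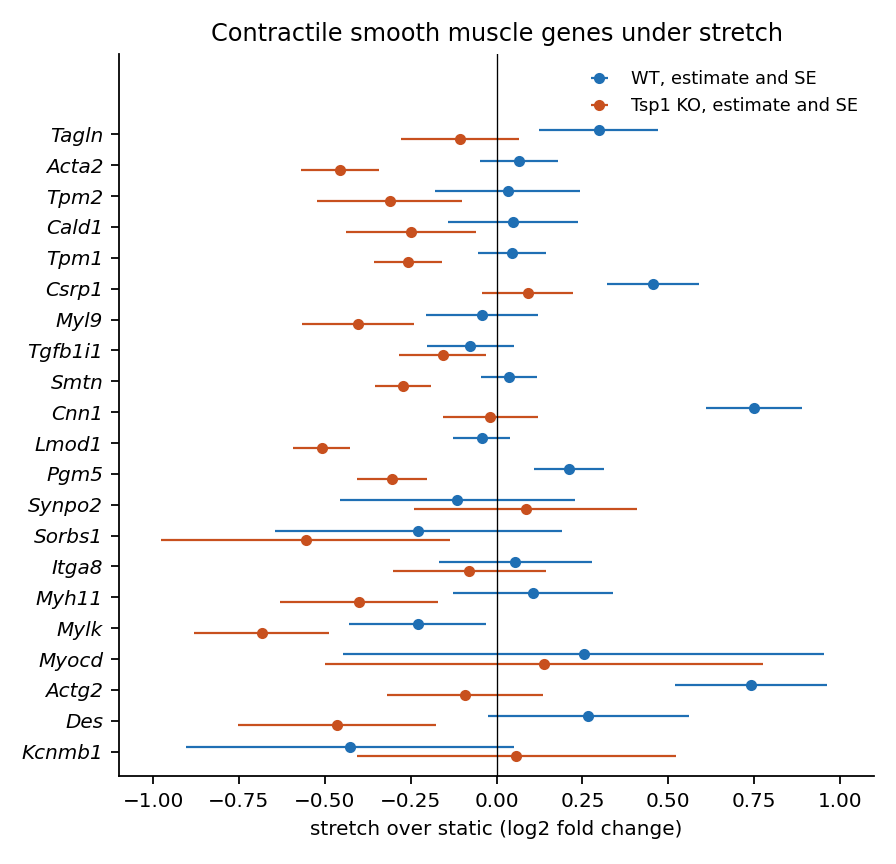
Log2 fold change with stretch (x axis) of the 21 contractile smooth muscle genes in WT (blue) and KO cells (orange), with SE, ordered by level. The KO value lies left of the WT value for 19 genes.

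Cholesterol synthesis genes also fell further in KO cells as a list, with a median interaction of -0.21 and 23 of 23 members below 0 (adjusted p = 3.23e-08, adjusted p = 0.215 with an estimated correlation). Smaller list differences were an actin and focal adhesion shift down (median -0.14, 0.00452 and 0.402 with an estimated correlation), ribosomal proteins down (median -0.20, 0.00763 and 0.858), heat shock genes down (median -0.14, 0.0196 and 0.566) and collagens up (median 0.10, 0.0387 and 0.858). Over all genes 0 members of these lists passed in edgeR, and 0 passed adjusted over the list alone. The actin list had 0.131 without WT stretch 1, 0.0591 without WT static 2 and 0.0600 without KO static 2. Without WT stretch 3 collagens had 0.904, heat shock genes 0.4001 and ribosomal proteins 0.985. Without WT static 1 these 3 had 0.524, 0.177 and 0.374, without KO static 3 they had 0.118, 0.118 and 0.882, without KO stretch 1 they had 0.506, 0.135 and 0.411, and without KO stretch 2 they had 0.116, 0.0788 and 0.195. In numbers 1 and 2 alone collagens had 0.146, and with the length trend removed and the block 0.0589. Collagens had 0.0777 without KO static 1, and collagens and heat shock genes each had 0.0525 without KO static 2. Immediate early genes had 0.0503 (0.0356 with the block, 0.577 with an estimated correlation as well). Interferon response genes had 0.0750, YAP/TAZ targets 0.233, cell cycle genes 0.377, p53 targets 0.415, the cytokine list 0.450, NRF2 targets 0.647, TGF-beta response 0.652, epithelial markers 0.645, mitochondrially encoded genes 0.706, integrins 0.709 and stress response genes 0.877.

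KO static cells differed from WT static cells in many genes and expressed genes that were near silent in WT. Anxa8 (ENSRNOG00000060949, chromosome 16 from 10417185 to 10432393), an annexin of epithelia, rose from 0.715 ± 0.47 to 81.4 ± 10.9 CPM (log2 fold change 6.77 ± 0.41, FDR 4.96e-07), and the urothelial membrane protein Upk1b from 1.92 ± 0.201 to 128 ± 7.83 CPM (6.06 ± 0.23, FDR 2.60e-08). Fndc1, the matrix proteoglycan Prelp, the aldehyde dehydrogenase Aldh3a1, Gda, the LIM protein Crip1, the innate immune receptor Tlr2, the lipopolysaccharide-binding protein Lbp and the interleukin-1 antagonist Il1rn rose by log2 4.54 to 5.48. Epha3, an ephrin receptor, fell from 71.7 ± 12.9 to 1.41 ± 0.219 CPM (-5.68 ± 0.26, FDR 6.61e-08), and Itgbl1 from 306 ± 18.6 to 20.2 ± 2.14 CPM (-3.92 ± 0.12, FDR 5.98e-09). The TGF-beta decoy receptor Bambi (-4.90), the protease Ctsh, Gsta4, the developmental regulators Mab21l1 and Barx1, Smtnl2 and the guidance receptor Robo2 (-3.89) fell as well. Olfml1 fell but only 22.3% of its reads were unique, and Barx1 lies in a stretch of chromosome 17 where KO levels were lower as a whole.

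At FDR 0.05, 3085 genes differed between KO and WT in static culture (1801 up, 1284 down), 1514 of them at least 2-fold (1021 up, 493 down). The block gave 5569 genes (2933 up, 2636 down). The authors' test has 2381 genes, of which 1562 differed at least 2-fold (1060 up, 502 down). Under stretch 3056 genes differed (1762 up, 1294 down), 1466 at least 2-fold (982 up, 484 down), and 5531 with the block (2822 up, 2709 down). The authors' test has 2446, of which 1556 differed at least 2-fold (1060 up, 496 down). Of the genes found in static culture and under stretch 1479 rises and 1019 falls were shared, where independent lists would share 214 and 112, and 0 were opposite. These comparisons share no library, but they share the same cells. All 20 named genes of each comparison kept FDR under 0.05 whichever library was left out.

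Under stretch most of the same genes led the KO to WT difference, though Tlr2, Lbp and Robo2 were no longer among those named by the rule. Anxa8 (0.671 ± 0.401 to 68.3 ± 10.3 CPM, 6.63 ± 0.40, FDR 4.72e-07), Upk1b, Fndc1, Gda, Prelp, Aldh3a1, Crip1 and Il1rn rose, joined by the coagulation inhibitor Tfpi (4.60 ± 0.241 to 143 ± 16.5 CPM, 4.96 ± 0.13) and the fibril-associated collagen Col14a1 (19.1 ± 4.86 to 534 ± 96.4 CPM, 4.80 ± 0.23). Epha3 (-5.71 ± 0.26), Gsta4, Ctsh, Barx1, Itgbl1, Bambi, Mab21l1, Smtnl2 and Spon1 (-3.94) fell, and Olfml1 with the same doubt.

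Interferon response genes, the cytokine and NF-kB list and p53 targets were higher in KO cells. Interferon response genes rose in 20 of 21 cases in static culture (median 1.43, adjusted p = 3.50e-13, adjusted p = 0.22 with an estimated correlation) and in 18 of 21 under stretch (19 adjusted over the list alone, median 1.41, 5.02e-12 and 0.225). The immunoproteasome gene Psmb8 (3.39 static), the antiviral genes Mx2 (3.03), Rsad2 (2.90) and Oas1a (2.93, 73.8% unique) and, under stretch, Irf7 (2.51) led. In the cytokine and NF-kB list 12 rose and 2 fell of 21 in static culture (1.99e-07, adjusted p = 0.0846 with an estimated correlation), and 13 and 2 under stretch (9.70e-07 and 0.103), with the chemokines Cxcl1 (23.8 ± 3.29 to 193 ± 4.30 CPM static, 3.02 ± 0.20), Cx3cl1 (2.73), Ccl2 (2.43) and, under stretch, Ccl7 (2.51), and the NF-kB cofactor Nfkbiz (2.72). Adjusted over the list alone, 13 rose and 2 fell in static culture and 14 and 2 under stretch. Of 17 p53 targets 12 rose and 1 fell in static culture (14 and 1 adjusted over the list alone, 15 and 2 with the block, 1.99e-07, adjusted p = 0.0129 with an estimated correlation, 0.149 with the block as well), and 11 and 1 under stretch (12 and 1, 9.70e-07, 0.0132 and 0.149). Gdf15, a stress-induced cytokine, rose from 1.55 ± 0.234 to 20.6 ± 2.68 CPM (3.72 ± 0.24), Ccng1, Zmat3 and, under stretch, Eda2r rose, and Tp53inp1 fell (-1.33 and -1.71).

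Immediate early genes were higher in KO cells, led by Klf4, a regulator of smooth muscle phenotype, at 11.0 ± 1.54 CPM in WT static and 221 ± 18.6 CPM in KO static cells (4.32 ± 0.13, FDR 5.98e-09, 85.3% unique). Egr2, Maff and Fosl1 rose too, so 12 rose and 1 fell of 25 (15 and 3 adjusted over the list alone and also with the block, 0.00130, 0.225 with an estimated correlation). Under stretch 9 rose and 2 fell (10 and 3 adjusted over the list alone, 12 and 5 with the block, 0.0209 and 0.423, 0.0546 without KO stretch 3 and 0.0998 in numbers 1 and 2 alone), with Atf3 down (-1.85). NRF2 targets rose for 6 of 15 in each condition (7 static, and 6 with 1 fall under stretch adjusted over the list alone), with Nqo1, a quinone reductase, at 281 ± 25.5 and 1139 ± 190 CPM in static culture. Their adjusted p was 0.0118 static (0.566 with an estimated correlation) and 0.0282 under stretch (0.617), with 11 and 10 rises and 1 fall each with the block, and under stretch 0.0887, 0.0681 and 0.0587 without WT stretch 1, WT stretch 2 and KO stretch 3. Cholesterol synthesis genes were higher in static KO cells, with 7 rises and 1 fall (10 and 1 adjusted over the list alone, median 0.31, 0.00408 and 0.541), among them Ebp, Lss (55.3% unique) and Sqle, and 13 rises with the block. Under stretch the list had 3 rises and 1 fall (0.709), and 5 and 3 with the block. Epithelial markers rose for 3 of 6 (0.0196 static and 0.0317 under stretch, 0.22 and 0.225 with an estimated correlation), with Cdh1 at only 1.80 ± 0.267 CPM in KO static cells, Krt8 at 44.3 ± 5.71 CPM, and Krt14 at 9.37 ± 2.21 CPM with 27.0% unique reads.

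**Figure D4:**
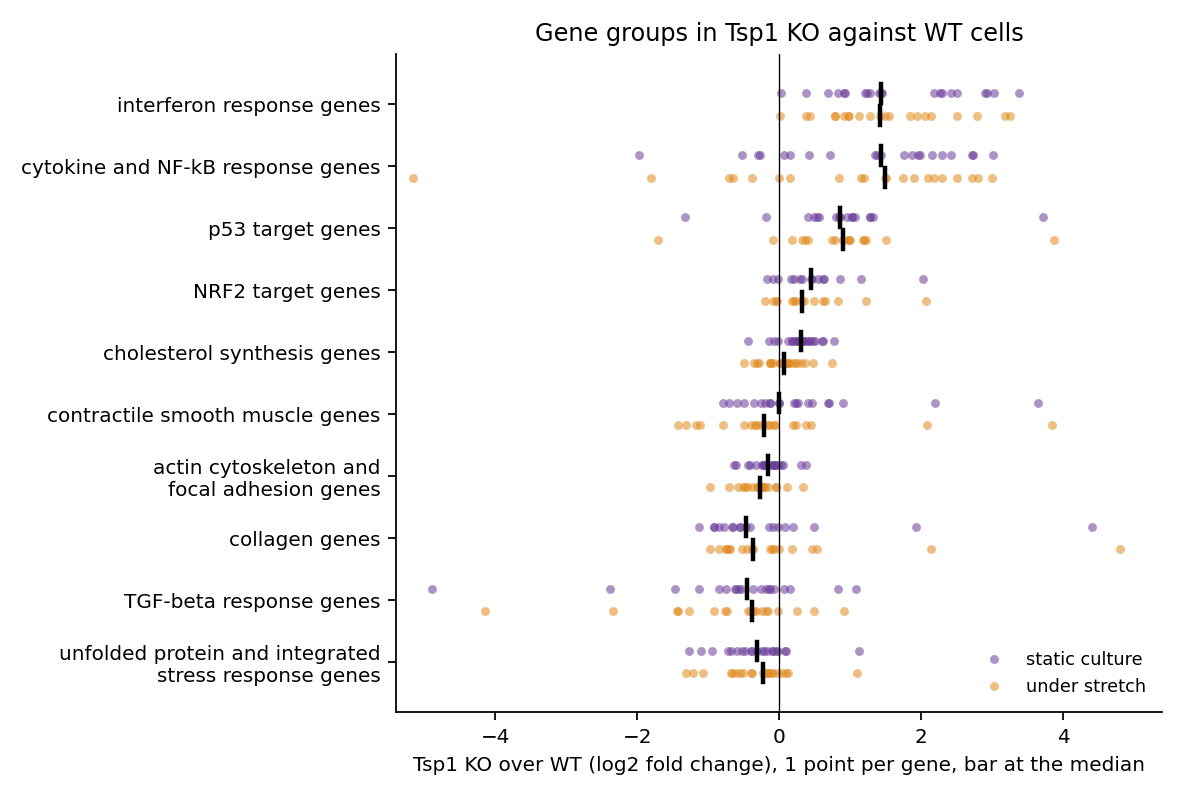
Log2 fold change of KO over WT (x axis) for the members of 10 gene lists, in static culture (purple) and under stretch (orange), where each point is a gene and the bar is the median. Medians are 1.43 and 1.41 for interferon response genes, 1.43 and 1.49 for the cytokine list, and -0.45 and -0.39 for TGF-beta response genes.

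TGF-beta response genes and stress response genes were lower in KO cells. In the TGF-beta list 7 fell and 2 rose of 20 in static culture (9 and 2 adjusted over the list alone, 0.00161, adjusted p = 0.0674 with an estimated correlation), and 8 fell and 1 rose under stretch (9 and 1, 0.000728 and 0.0504), with Bambi, the matrix protein Tgfbi (-2.39 static), Inhba (-1.48) and Tgfb3 (-1.13). Bambi, Tgfbi and Inhba lie on chromosome 17, Tgfbi in the stretch with lower KO levels. With the block 13 members fell in each condition, and 2 and then 3 rose. In the unfolded protein and integrated stress response list 8 fell and 1 rose of 21 static (11 and 1 adjusted over the list alone, 0.00153 and 0.635 with an estimated correlation), and 9 and 1 under stretch (10 and 1, 0.00309 and 0.641), with Trib3 (-1.27), Chac1 (-1.11) and Psat1 (-0.94) down and Ddit4 (1.12) up. With the block 13 fell static and 11 under stretch. Actin and focal adhesion genes were lower in KO cells under stretch (6 fell and 1 rose of 20 over all genes and adjusted over the list alone, 0.00497 and 0.402 with an estimated correlation), and 15 fell with the block. In static culture 3 fell and 2 rose (8 and 2 with the block, 0.120, 0.0495 with the block, and 0.764 with an estimated correlation as well). The serum response factor Srf fell in static culture and under stretch (-0.64 and -0.98).

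Matrix and contractile genes of KO cells moved both ways, and camera gave their lists no adjusted p under 0.05. Type I and III collagen fell, Col1a1 from 36949 ± 5724 to 19447 ± 343 CPM (-0.93 ± 0.18) and Col3a1 by a log2 fold change of -1.14, while Col14a1 (4.41) and Col8a1 (1.93) rose. The list gave 2 rises and 7 falls of 19 static (0.0572) and the same numbers under stretch (0.241), with 2 and 9 and then 3 and 8 adjusted over the list alone, and 3 and 11 and then 4 and 10 with the block. Upper-quartile scaling gave 0.0461 static. Under stretch its median was -0.37 but its mean was 0.07. Elastin (Eln, -1.77) and Fbln5 (-1.82) fell while Efemp1, Mfap5 and, under stretch, Fbn1 (1.93) rose, giving 9 rises and 4 falls of 22 static (0.450) and 10 and 5 under stretch (0.377). Thbs2, a relative of Thbs1, rose to 5.54 ± 0.204 from 1.99 ± 0.289 CPM (1.47 ± 0.20, and 2.13 ± 0.20 under stretch), Comp and Tnc rose, Postn fell (-1.18), and the Tsp1 receptor Cd47 rose under stretch (0.98). The matricellular list had 4 rises and 2 falls in each condition (0.629 and 0.382), and with the block 8 and 3 static and 7 and 3 under stretch. Mmp2 rose (2.01) and Adamts1 fell (-1.51) among proteases, with 5 rises and 3 falls in each condition (0.645 and 0.491), and 9 and 5 in each with the block. The rotation test fry, which sets no list against the other genes, gave proteases up (adjusted p = 0.00721 static and 0.00349 under stretch), matricellular genes up under stretch (0.00554), contractile genes down under stretch (0.000748) and fibroblast markers up (1.25e-06 static and 1.33e-06 under stretch).

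Contractile genes gave 5 rises and 2 falls of 21 in static KO cells (0.788, and 8 and 5 with the block), with Synpo2 (3.65), Myocd (2.19) and Mylk (0.90) up and Acta2 (-0.79) down. Here the median was -0.0012 and the mean 0.29. Under stretch 2 rose and 6 fell (0.0728, and 0.0374 in numbers 1 and 2 alone), with Actg2 (-1.43), Acta2 (-1.31) and Lmod1 (-1.18) down. Integrins had 3 rises and 3 falls of 16 (0.583, and 4 and 6 with the block), and 3 and 5 under stretch (0.480), with Itga9 (-4.99) and Itga3 (-1.63) down and Itgb4 (2.45) and Itga7 (1.70) up. YAP/TAZ targets had 5 rises and 5 falls of 21 static (0.464) and 3 and 7 under stretch (0.309), and 6 and 8 and then 7 and 8 with the block, with Igfbp3 (-3.76) and Ccn1 (-0.84) down and Gadd45a (0.99) and Fjx1 (0.64) up in static culture. Among Hippo components Wwc1 rose (1.44) and Tead2 fell (-0.83), with 2 rises and 5 falls of 24 static (0.311) and 3 and 4 under stretch (0.384), and 4 and 11 and then 4 and 9 with the block. Osteochondrogenic markers had Acan down (-2.41) and Mgp up (1.74), with 2 rises and 4 falls of 9 (0.417), and 3 and 4 under stretch (0.387). Fibroblast markers had Fap (2.78), Clec3b (2.33) and Fmod (1.95) up and Ogn down (-2.50, but 4.36% unique), with 4 rises and 2 falls of 10 (0.124), and 4 and 3 under stretch (0.124), while fry gave them up in each condition.

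Camera gave the remaining lists no adjusted p under 0.05 between KO and WT cells. Glycolysis and hypoxia genes had Ndrg1 up (0.95) and Car9 down (-0.87), 4 rises and 5 falls of 22 static (0.886) and 5 and 5 under stretch (0.930), and 8 and 7 and then 8 and 8 with the block. Cell cycle genes had 4 rises and 1 fall of 26 static (0.990) and 3 and 1 under stretch (0.679), with Tyms and Ccne1 up in each. The block turned this balance, with 5 rises and 6 falls static and 4 and 9 under stretch. Heat shock genes had Hspb8 down (-1.01) and Cryab up (0.67) in static culture (0.671), and Hspb8 down under stretch (0.627), with 5 rises and 1 fall and then 2 and 2 with the block. In mitochondrially encoded genes (0.402 and 0.309) and ribosomal proteins (0.731 and 0.366) 0 members passed in edgeR. With the block 3 ribosomal proteins rose static, 2 fell under stretch (list 0.0282 with the length trend removed as well), and 2 mitochondrial genes fell under stretch. Of the leukocyte markers Laptm5 fell in each condition and Cd74 rose under stretch (0.770 and 0.725, with 2 rises and 1 fall under stretch with the block), of the endothelial markers Tek fell in static culture (0.703 and 0.705, with 1 rise and 2 falls static and 0 and 1 under stretch with the block), and of the adipocyte markers Lpl fell in each condition and Cebpa rose in static culture (0.782 and 0.662). Over the 140 list tests 40 had an adjusted p under 0.05, 5 of these kept it with an estimated correlation (cholesterol synthesis in each stretch comparison, p53 targets in each KO comparison and contractile genes in the interaction), and 0 did so with the block and an estimated correlation together. Median, mean and test direction differed in sign for 23 tests, none of them among the 40.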

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

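The tests of the contractile list below were chosen after its difference between the genotypes had been noticed in a first fit, and they were fixed before their own values were seen. The 8 results here were picked out because a test of the difference itself found the stretch response to differ between WT and KO cells. Groups of 3 libraries were not tested for single samples far from the others.

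As lists, contractile smooth muscle genes (adjusted p = 4.06e-11), cholesterol synthesis genes (3.23e-08), actin and focal adhesion genes (0.00452), ribosomal proteins (0.00763) and heat shock genes (0.0196) responded lower in KO cells, and collagens (0.0387) higher. Of these 6, only contractile genes kept an adjusted p under 0.05 with an estimated correlation (0.0129), and with the replicate block and an estimated correlation together they had 0.246. With the replicate block, Aldh1a3 (FDR 0.00357) rose less in KO cells and Vegfc (FDR 0.0353) did not fall there as it did in WT. Without the block the FDR of both was 0.827. Without the block the real grouping of the libraries gave 0 genes for the interaction. With a count of 0 all 100 of 100 splits must give as many (the highest gave 1), so the splits decide nothing here.

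The contractile difference had a median of -0.36. In libraries numbered 1 and 2 alone it was -0.33, with 20 of 21 members below 0. This argues against the number-3 libraries as its source. A 95% bootstrap interval over the members ran from -0.46 to -0.30. The members share the same libraries, so this interval does not measure the spread between libraries. Against 10000 lists matched on exon length and level, whose medians lay between -0.10 and 0.05 in the central 95%, the list stood at -0.36, so a length bias is an unlikely source. The difference was spread over the list, as 90.5% of the members lay below 0 and the median was -0.33 without the 4 largest. The list was picked for this same difference, so these values describe it and are no separate test. What stays open is a clonal difference, since KO cells were grown from single cells, and separate handling of the KO stretch cultures, so a role of Tsp1 in keeping contractile expression under stretch may be stated only as a hypothesis, which independent KO clones or return of Tsp1 to KO cells would test.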

How the results depend on the processing

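The 2-level block for number 3, the fit without number 3 and the removal of a length trend were chosen after the data were seen, and the other alternatives before. With 3 libraries per group and number effects as large as these, the test without the block recovered few simulated 1.5-fold changes (22.4% for WT stretch and 11.9% for KO against WT in static culture). The sign of Thbs1 in each comparison held in every alternative run. The stretch counts and slopes did not hold, and the KO to WT counts at FDR 0.05 grew with the block while those at 2-fold stayed within 1.5 times of the others except on log2 RPKM. The cause was not tested where none is given.

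DESeq2 gave 360 genes for WT stretch (50 at least 2-fold), 294 for KO stretch (47) and 9 for the interaction (4). It shared 154 genes between the stretch responses, gave slopes of 0.122 for KO on WT and -0.0315 for WT on KO, a reversal, and an FDR of 0.01002 for Thbs1 in WT stretch (-0.89). No filter beyond 1 read gave 76 genes for KO stretch and a KO on WT slope of 0.426. With only the 2 groups compared in the fit, and so fewer libraries to estimate the spread, WT stretch had 10 genes (6) and KO stretch 0 (0), 0 genes were shared, the KO on WT slope was 0.527, and the reverse slope had no genes and so no value. RLE and upper-quartile scaling gave that slope as 0.517 and 0.540, and the stricter filter gave slopes of 0.476 and 0.390.

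The replicate block gave 944 genes (59) for WT stretch, 656 (53) for KO stretch, 5569 and 5531 for KO against WT in static culture and under stretch, and 2 (1) for the interaction. It shared 379 genes, had slopes of 0.140 and 0.374, and gave Thbs1 -0.90 (FDR 2.88e-05) in WT stretch and -0.57 (FDR 0.000609) in KO stretch. The 2-level block gave, in the same order, 1030 (68), 720 (57), 5700, 5651 and 6 (2), 416 shared, slopes of 0.0981 and 0.383, and Thbs1 -0.90 (FDR 1.03e-05) and -0.56 (FDR 0.000351). Numbers 1 and 2 alone gave 528 (65), 439 (57), 4739, 4985 and 3 (3), 224 shared, slopes of 0.327 and 0.159, and Thbs1 -0.86 (FDR 0.000302) and -0.52 (FDR 0.00705). The length trend removed with the block gave 1194 (64), 893 (63), 5751, 5910 and 9 (2), 507 shared, slopes of 0.0985 and 0.377, and Thbs1 -0.87 (FDR 7.67e-06) and -0.55 (FDR 9.66e-05). Taking out the number effects lowered the spread, with a common dispersion of 0.0096 after the block.

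On log2 RPKM the 2-fold counts were smaller, as a pseudocount shrinks folds of low genes. With a pseudocount of 0.5 they were 10 for WT stretch, 16 for KO stretch, 851 and 898 for KO against WT, with slopes of 0.391 and 0.543. With 0.1 WT stretch had 14 and the slopes were 0.502 and 0.603. With 1 the counts were 8, 9, 695 and 686 and the slopes 0.342 and 0.526. Without a filter WT stretch had 65 genes (10) and KO stretch 56 (12), 906 and 926 genes were at least 2-fold in KO against WT, 28 were shared, and the slopes were 0.391 and 0.523.

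Leaving out each library in turn gave 23 to 118 genes for WT stretch (8 to 30 at least 2-fold), 24 to 122 for KO stretch (12 to 26), 2439 to 3226 for KO static (1361 to 1543), 2350 to 3192 for KO under stretch (1322 to 1495), 0 to 0 for the interaction at FDR 0.05 and also at 2-fold, 15 to 37 shared, and slopes of 0.246 to 0.654 and 0.182 to 0.924. Thbs1 stayed between -1.03 and -0.71 in WT stretch, -0.69 and -0.38 in KO stretch, -2.41 and -2.11 in KO static, -2.11 and -1.75 in KO under stretch, and 0.15 and 0.51 in the interaction. A group left with 2 libraries is assumed to vary like the others.

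Of the list tests, the block gained 7 adjusted p under 0.05 and lost 1, all given with the results, and it changed no other list call. The estimated correlation lost 35, the block with an estimated correlation lost all 40, fry lost 19 and gained 8, and RLE scaling changed 0. Numbers 1 and 2 alone lost 9 and gained 4, the length trend removed with the block lost 3 and gained 5, the 2-level block lost 1 and gained 6, log2 RPKM lost 1 and gained 2, and upper-quartile scaling gained 1. Leaving out members of more than 1 list tested nothing, because no tested gene is in more than 1 list. Leaving out single libraries lost 45 and gained 27. There 3 changed direction, collagens (adjusted p = 0.904) and ribosomal proteins (0.985) of the interaction without WT stretch 3 and ribosomal proteins in KO stretch (0.0342) without KO stretch 3. Over all single libraries left out these lists ranged from 0.000201 to 0.904, 4.54e-07 to 0.985 and 0.00333 to 0.737. No named gene changed direction where either fit passed FDR 0.05, and 264 of their tests lost FDR 0.05 under the other alternatives and 453 without single libraries. In the same order 5941 and 4635 tests kept their call or lack of one, and 18 and 0 gained a call.

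The 6 libraries of each pairwise comparison can be parted 3 against 3 in 10 ways, too few for a share under 0.05. In each, 1 split gave as many genes as the real one, the real split itself. The real counts were 110 (27 at least 2-fold), 118 (28), 3085 (1514) and 3056 (1466), and the highest other was 0, also among the 4 splits that part all 3 pairs of library numbers. With the block the highest other was 1 in each stretch comparison and 0 in each KO comparison. Every other split mixes the 2 groups on both sides, so a difference between the groups becomes spread within a side and lowers the count. Low counts in the other splits are therefore built in where the groups differ, and no conclusion is drawn from them.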

Other observations

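The patterns of the chromosome 17 region and of the number-3 libraries were noticed in first fits and then tested on the same data, and the copy-loss test was chosen only after the region's values were seen. The Thbs1 and cholesterol tests were written before their intron reads were examined.

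Genes in the first 45 Mb of chromosome 17 were lower in KO cells. Of 171 genes there with a mean log2 CPM of at least 2, the median log2 fold change was -0.27 in static culture and -0.31 under stretch. Each KO library gave a region median between -0.27 and -0.30, and WT libraries between -0.04 and 0.05. Of 50 windows of 171 genes along the genome, the region's included, the lowest other gave -0.06 in static culture and -0.10 under stretch, and the rest of chromosome 17 had -0.08 in each condition. The best single breakpoint lay at 26.9 Mb rather than at 45 Mb. Tgfbi, Barx1, Ogn, Pdlim7 and Msx2 lie in the region, but a shift of this size does not account for a fall such as that of Tgfbi (-2.39). Both conditions come from the same cells, so they are not independent.

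The central 95% of 10000 gene sets matched on length and level ran from -0.04 to 0.07 in static culture (region -0.27) and from -0.07 to 0.04 under stretch, which argues against a length or level bias. The shift was spread over the region, as 80.1% of its genes lay below 0 in static culture and 82.5% under stretch, against 49.9% and 53.6% on other chromosomes. The region was picked for this same shift, so these shares describe it and are no separate test. A bootstrap over the region's genes, which are not independent samples, put the lower bound of the median at -0.37. This stays above the fall near 1 log2 unit that loss of 1 of 2 copies in every KO cell with proportional mRNA would need. The medians were already known when this test was chosen. The bound covers all 45 Mb, while the best breakpoint lay at 26.9 Mb, so it does not speak to loss of a shorter stretch. The upper quartile was lower by at least 0.26 (a shift of -0.26), as a shift of the whole region would give. The parts on either side of 26.9 Mb were not tested apart, so a shift of only a part of the region stays open. A loss in part of the KO cells, loss of a shorter stretch, a gain in WT cells or regional silencing may each explain the lower levels. RNA levels alone do not part them, while the DNA copy number of both cell lines would.

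The number-3 libraries of all 4 groups differed from numbers 1 and 2 in 7427 genes. After the trend with exon length was removed 4352 of these (58.6%) still differed, so gene length is not the whole difference, though long genes were lower in number 3. After every library was thinned to 16.8e6 reads 6843 (92.1%) still differed, which argues against depth. A separate preparation, RNA quality or culture of the number-3 set may underlie the difference, which the labels do not record. No biological explanation was tested.

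Thbs1 intron reads, 377 to 4114 per library, tested whether transcription as well as mRNA was lower in KO cells. KO and WT libraries of the same number in the same condition were paired, which gave 6 pairs. The check of library numbers found no clear pairing for most numbers, so the choice of pairs is partly arbitrary. All 6 pairs come from the same KO and WT cells and are not independent repeats of the knockout. The p-value below therefore describes only these libraries. The mean log2 ratio of KO over WT was -1.43 (SD 0.44, lower in 6 of 6 pairs of libraries, exact two-sided sign-flip p = 0.03125, the smallest that 6 pairs allow), against -2.04 in exons. Loss of spliced mRNA alone with unchanged transcription would leave the intron reads in place, but some reads counted as intronic may come from the same transcripts, so this ratio does not decide it.

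Cholesterol synthesis genes were tested for lower transcription under stretch through their summed intron reads, 3452 to 7288 per library. Stretch and static libraries of the same number in the same genotype were paired, which gave 6 pairs, again without clear pairing for most numbers. Pairs of a genotype share the same cells and are not known to be separate cultures. Here too the p-value describes only these libraries. The mean log2 ratio of stretch over static was -0.60 (SD 0.12, lower in 6 of 6 pairs, exact two-sided sign-flip p = 0.03125, the smallest possible), with -0.52 in WT and -0.67 in KO cells, against -0.74 in exons. Lower transcription under stretch would lower the intron reads, and they fell in both genotypes. Some reads counted as intronic may come from the same transcripts, so here too the ratio does not decide it. Labelling of new RNA would test it, as processing of the transcripts was not measured.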
